A study of Mus musculus with 12 samples.

How the data were processed

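Messenger RNA levels were measured by RNA sequencing in 12 libraries from mouse skin. The cells fall into 3 compartments, named IFE, ORS and HFSC in the labels, and each compartment holds 2 control libraries and 2 libraries labelled Egfr knockout. ORS stands for outer root sheath and HFSC for hair follicle stem cells. The labels pair IFE with the inner root sheath, although the abbreviation is widely used for interfollicular epidermis. The abbreviation is kept here, and the marker levels that bear on the choice are given in the results. Controls carry a floxed Egfr allele that is not deleted, the IFE and ORS knockout genotype is written as an epidermal deletion, and the HFSC knockout genotype as a deletion tied to Lgr5. Per the labels' protocols, RNA was isolated with a PicoPure kit and copied with a SMARTer Ultra kit, and the series text gives paired reads of 150 bp. The libraries are named by the letter and number that open their titles (IFE control E341 and E360, IFE knockout E358 and E359, ORS control E341 and E344, ORS knockout E358 and E359, HFSC control L94 and L136, HFSC knockout L95 and L97). No label says that libraries of a group come from separate animals, so p-values measure the spread between these samples, which may be technical. The exception is ORS control E341 and E344, which differ in sex by their reads (29 and 41490 Xist reads) and so cannot come from the same animal. Replicates were compared before averaging, and the counts of every replicate pair differed far beyond sampling noise (chi-square per degree of freedom between 47.0 and 159.6), so no pair is 1 library deposited again. This does not show that the libraries are independent.

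The deposited values are log2 reads per 1e6, 1 value per gene and library for 25965 genes. The divisor is a library total of 39.9 to 60.9 M that is larger than the sum over genes, and a gene without a read holds the value of 0.9 read. The submitters' processing notes name Trim Galore, DESeq2 and the mm10 genome build, without their roles. The aligner, the counter and the gene annotation are not given in the sources used here, nor is whether the counting used strand. Values above the floor of each library were whole multiples of 1 read for at least 99.99% of genes, within 0.2 reads, so whole reads per gene were recovered from the deposited log2 values. Reads in genes came to 11.4 to 27.7 M per library. All 13 mitochondrially encoded genes listed had 0 reads in all 12 libraries. Of the gene names, 22600 (87.0%) were found in the GENCODE annotation of mm10, and 99.64% of these overlapped the annotated gene. Genes with near-identical copies (the Lce1, Sprr2, Stfa and Serpinb3 families, Krt6a with Krt6b, Krt16 with Krt17) and the antisense pair of Xist and Tsix may share reads, so their separate values are uncertain.

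The test planned before the data were examined, the quasi-likelihood count test of edgeR, was not used. The deposited unit is log2, although the recovered reads would have allowed a count test. The moderated test of limma 3.58.1 (R 4.3.3, statmod 1.5.0, trended and robust prior) was used on log2(CPM + 0.5), where CPM is reads per 1e6 reads in genes after TMM scaling (trims of 30% on ratios and 5% on levels). Fold changes on this scale understate the change of low genes. A gene was tested if it had at least 10 reads, at the median library size, in at least 2 libraries and at least 15 reads in total. The 8 IFE and ORS libraries were fitted together as 4 groups (4 residual degrees of freedom), and the 4 HFSC libraries alone (2 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The comparisons were knockout against control in each compartment, ORS against IFE over both genotypes, and the difference of the IFE and ORS knockout effects. On simulated data with 200 changed genes, the fits recovered 87.9% of 8-fold changes in IFE, 81.8% in ORS and 98.5% in HFSC. For 2-fold changes they recovered 14.9%, 11.9% and 37.3%. These fits made 4, 6 and 2 false calls. For ORS against IFE the shares were 98.5% and 44.8% with 5 false calls, and for the difference of effects 68.2% and 1.5% with 4 false calls. Changes were planted only in genes averaging at least 5 CPM, and each gene was given the mean spread of genes at a similar level. The shares therefore do not carry over to real genes, which have their own spread. Egfr, at 0.119% of control in IFE and 11.3% in ORS, was not called in either.

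The design also held 34 gene lists of pathways, differentiation programmes and other cell types, fixed before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over 97 tests of the knockout comparisons together, over 33 for ORS against IFE and over 33 for the difference of effects. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. That adjustment does not correct for the number of lists, so single members may pass in some lists by chance. Genes are named by a rule fixed at the same time: Egfr, Lef1, Trp53 and Mki67 in each compartment, the 8 largest rises and 8 largest falls among genes called with at least 5 CPM and no overlap of the groups, up to 4 members of a list with the lowest p, and the 5 lowest p per direction for the difference of effects. Steap4, Xist, Krt1 and Krt10 in the IFE comparison, Krt1 and Krt71 in ORS against IFE, and Spry2 in HFSC are outside the rule and were chosen after their values were seen. Some genes that the rule would name are not reported here. Values are given in CPM as mean ± SD (marker levels of the opening paragraph before TMM scaling), with 2 libraries per group unless stated. Limits on 0 reads use 3 reads per library and, like the 95% intervals of read counts, cover counting error only.

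The alternatives were another scaling, no filter or a filter at 50 reads, limma-voom, other sets of libraries in the fit, the title number as a block, pseudocounts of 0.1 and 1, the deposited scale, a term for the sex read from Xist and Y-linked genes, removal of those genes, and leaving out each library in turn. The alternatives on pseudocount, deposited scale, sex and removal of sex-linked genes were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.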

Results

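RNA from IFE, ORS and HFSC cells of mouse skin was sequenced in 12 libraries, with 2 control and 2 knockout libraries per compartment. The series is about the epidermal growth factor receptor EGFR in hair shaft differentiation, and the comparisons ask which transcripts differ when the receptor gene is deleted. Reads in genes were 11.4 to 13.2 M per IFE library, 24.7 to 27.7 M per ORS library and 11.5 to 16.8 M per HFSC library. They made up 27.8% to 29.6% of the library total in IFE, 50.6% to 54.6% in ORS and 26.9% to 28.9% in HFSC. Marker genes set the compartments apart, here in reads per 1e6 reads in genes before TMM scaling, unlike the CPM of all later paragraphs. Cd34, a surface marker of bulge stem cells, was at 1727 ± 585 CPM in HFSC control libraries and 3.71 ± 0.69 CPM in ORS control libraries, with 0 reads in IFE. Krt10, a keratin of suprabasal epidermis, was at 988 ± 497 CPM in IFE control libraries and 47.7 ± 26.8 CPM in ORS control libraries. Krt25, a keratin of the inner root sheath, had 0 reads in all 4 IFE libraries. Krt28 of the same list also had 0 reads there, and Krt71 reached at most 6.53 CPM, while Krt1 was at 1153 ± 660 CPM in IFE controls. These keratin levels argue against inner root sheath cells as the main content of the IFE libraries. Other genes of that list were present, such as Gata3 and Tchh (13.5 ± 0.12 CPM in IFE knockouts). Markers of other cell types were mixed. Ptprc, the pan-leukocyte marker CD45, had 0 reads in all 12 libraries, whereas Cd74, an antigen presentation gene, reached 44.2 CPM in HFSC and Csf1r, a macrophage receptor, 27.8 CPM. Among fibroblast genes, Col1a1 reached at most 19.1 CPM, Dcn 125 to 267.5 CPM across IFE libraries and Sparc 1175 CPM in its highest library, so a share of other cells is not ruled out.

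Egfr itself (chromosome 11, 16752203 to 16918158, + strand in mm10, protein coding) was lost from the IFE knockout libraries, reduced in the ORS knockout libraries and largely kept in the HFSC libraries labelled knockout. In IFE it was at 136.5 ± 29.3 CPM in controls. Knockout library E358 had 0 reads, which allows up to 0.243 CPM, and knockout library E359 had 4 reads (0.326 CPM, 0.238% of the control mean). The mean of both was 0.119% of control. In ORS the level was 260.1 ± 17.6 CPM in controls, 3.71 CPM in knockout E358 and 55.2 CPM in knockout E359. The knockout mean of 29.5 ± 36.4 CPM was 11.3% of control. In HFSC the level was 406.3 ± 28.6 CPM in controls and 329.7 ± 3.1 CPM in the libraries labelled knockout, or 81.1% of control. The log2 fold changes were -7.72 (SE 0.952, adjusted p = 0.0806) in IFE, -4.09 (SE 0.952, adjusted p = 1) in ORS and -0.30 (SE 0.154, adjusted p = 0.694) in HFSC, all from limma. These p are adjusted over all genes, although Egfr was named before the data were examined. The unadjusted limma p were 8.33e-06 in IFE, 0.00146 in ORS and 0.0913 in HFSC. IFE and ORS share 1 estimate of the spread, which includes the wide gap between the 2 ORS knockout libraries. The HFSC fold was 0.813 with a 95% interval of 0.633 to 1.04. In a limma fit of all 12 libraries the Egfr effect differed between HFSC and IFE by 7.42 (SE 1.16, unadjusted p = 3.65e-05, adjusted p = 0.0855). Between HFSC and ORS it differed by 3.79 (SE 1.16, unadjusted p = 0.0069, adjusted p = 0.854). The IFE value passed the threshold with a filter at 50 reads (adjusted p = 0.0463), with the IFE libraries alone (0.0391) and in the fit of all 12 libraries (0.0057). Its adjusted p ranged from 0.0057 to 1 over the alternatives. Without knockout library E359 its log2 fold change was -8.09, resting on 1 knockout library. Because the HFSC libraries labelled knockout kept most Egfr transcript, directions drawn from them below refer to the labels.

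**Figure D1:**
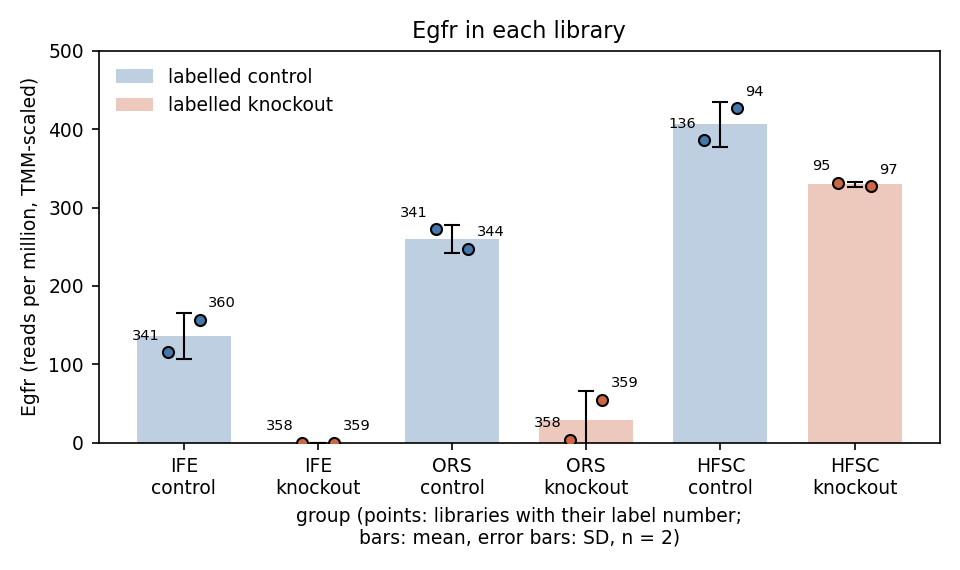
Egfr level in CPM for each library, by compartment and genotype label, with group means and SD. IFE knockout libraries sit at 0 and 0.326 CPM, ORS knockout libraries at 3.71 and 55.2 CPM, and HFSC libraries labelled knockout at 332 and 328 CPM.

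Transcripts of sex-linked genes separated the libraries across the genotype labels. Xist, the X-inactivation RNA, had 11 to 96 reads in 5 libraries and 5699 to 43878 reads in the other 7. The 5 libraries with little Xist (both IFE controls, ORS control E341 and both HFSC libraries labelled knockout) had 3609 to 11873 reads in the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and the other 7 had 0 to 28. Genotype therefore coincided with sex in IFE, where controls were male and knockouts female, and in HFSC, where controls were female and the libraries labelled knockout male. In ORS, control E341 was male and the other 3 libraries were female. Within IFE or HFSC alone, sex and genotype cannot be told apart.

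**Figure D2:**
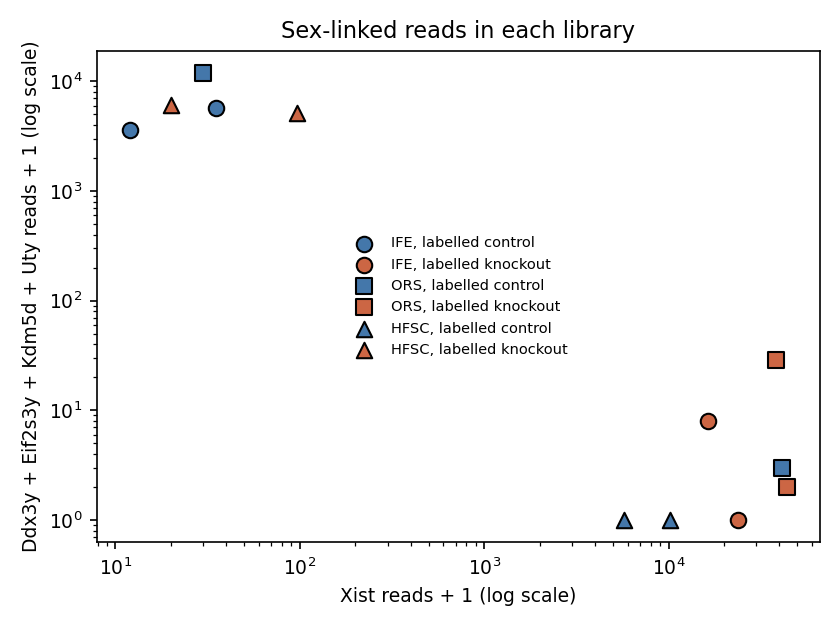
Reads of Xist against summed reads of 4 Y-linked genes in each library, each plus 1 on log axes. The 5 male libraries hold 11 to 96 Xist reads, and the 7 female libraries hold at least 5699.

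In IFE, genes of the cornified envelope, the protein shell of dead surface keratinocytes, were lower in knockout than in control libraries, as were genes of the stress and hyperproliferative keratinocyte list. Of 24 tested cornified envelope genes, 23 had a lower fitted level, with a median log2 fold change of -2.55, also with genes at 0 reads set to their bound. Lce1h, a late envelope protein, was at 28.8 ± 29.6 CPM in controls and 0.041 ± 0.058 CPM in knockouts, Lce1a1 at 61.1 ± 72.6 and 0.893 ± 0.112 CPM, Lce1g at 45.5 ± 58.3 and 0.936 ± 1.32 CPM, and Sprr2a3, a small proline-rich protein, at 10.2 ± 5.2 and 1.10 ± 1.44 CPM. None of the list's genes passed the test singly, over all genes or adjusted over the list alone. As a group the list was lower by camera (adjusted p = 1.25e-05, and adjusted p = 0.837 with an estimated correlation). The group call was lost without IFE control E341 (adjusted p = 0.417, median -1.19) and kept without IFE control E360 (adjusted p = 9.42e-10, median -4.44). The mean log2 level of the list was 4.76 in control E341, 1.75 in control E360, 0.93 in knockout E358 and 0.73 in knockout E359.

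**Figure D3:**
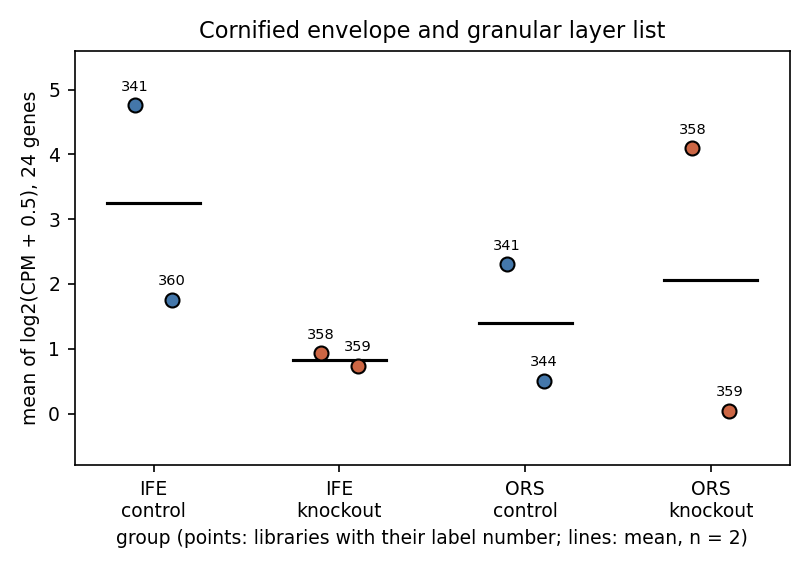
Mean log2(CPM + 0.5) of the 24 tested cornified envelope genes in each IFE and ORS library. IFE control E341 (4.76) and ORS knockout E358 (4.10) stand above the other libraries of their groups (1.75 and 0.04).

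The stress and hyperproliferative list was lower as a group in IFE (14 tested, camera adjusted p = 0.00422, and adjusted p = 0.837 with an estimated correlation). Adjusted over the list alone, 1 member was higher and 6 were lower. Serpinb3a and Serpinb3b, serpin protease inhibitors of activated keratinocytes, were at 10.6 ± 3.4 and 11.2 ± 3.0 CPM in controls and had 0 reads in knockouts, at least 43.5-fold and 46.1-fold lower against 3 reads per library. Krt6b, a keratin of stressed epidermis, was at 7.42 ± 4.19 and 0.325 ± 0.231 CPM, whereas Krt17, another stress keratin, was at 2582 ± 828 and 4333 ± 928 CPM. The call was lost without control E341 (adjusted p = 0.436), without control E360 (0.0543) and without knockout E359 (0.199). The sex-linked list was the remaining IFE list called (Down, adjusted p = 0.0129, adjusted p = 0.837 with an estimated correlation), with 1 member higher and 4 lower over the list alone. Y-linked Eif2s3y fell from 141.5 ± 8.6 to 0.081 ± 0.115 CPM over the list alone, Kdm5d was at 36.2 ± 5.3 and 0.041 ± 0.058 CPM, Ddx3y at 188.0 ± 66.8 and 0.163 ± 0.230 CPM, Uty at 39.0 ± 31.0 CPM with 0 reads in knockouts, and Xist at 1.93 ± 1.32 and 1639 ± 424 CPM. That call was lost without control E341 (adjusted p = 0.16), knockout E358 (0.0656) or knockout E359 (0.199).

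Among other IFE groups, 28 p53 target genes were tested, and 3 were higher and 1 lower when adjusted over the list alone. Ddit4l, an inhibitor of mTOR signalling, had 0 reads in controls and 6.25 ± 0.59 CPM in knockouts, at least 23.1-fold higher. Rrm2b, a ribonucleotide reductase subunit, was at 5.29 ± 2.88 and 37.6 ± 24.8 CPM, Perp, a desmosomal membrane protein, at 1671 ± 319 and 3090 ± 540 CPM, and Apaf1, the apoptosome scaffold, at 24.2 ± 9.8 and 3.78 ± 2.83 CPM. The p53 list did not move as a group (camera adjusted p = 0.579). In the lipid barrier and protease list, 0 members were higher and 2 lower over the list alone: Spink5, an inhibitor of epidermal kallikreins, at 26.2 ± 17.5 and 0.081 ± 0.115 CPM, and Abca12, a lipid transporter, at 5.11 ± 0.98 CPM with 0 reads in knockouts (at least 21-fold lower). In the outer root sheath and stem cell list Dkk3, a secreted Dickkopf family protein, was the 1 member lower over the list alone (24.5 ± 9.2 and 2.32 ± 2.13 CPM), and Lgr5 had 0 reads in controls and 2.24 ± 2.71 CPM in knockouts. The suprabasal list was not called (adjusted p = 0.0625), with Dsc1, a desmosomal cadherin, at 10.9 ± 12.7 and 0.122 ± 0.173 CPM and Skint3 at 2.40 ± 1.48 and 0.163 ± 0.230 CPM. The abundant suprabasal keratins Krt1 and Krt10 were at 1204 ± 704 and 1032 ± 531 CPM in controls and 1034 ± 351 and 972.7 ± 162.8 CPM in knockouts, without a stable direction. The DNA replication list was not called either (adjusted p = 0.0764), with Mcm2, a replicative helicase subunit, at 38.6 ± 2.3 and 88.3 ± 37.2 CPM, Cdc45 at 13.3 ± 16.0 and 49.0 ± 6.9 CPM, and Mcm10 at 16.6 ± 8.6 and 2.72 ± 1.79 CPM.

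By limma, 0 of 14449 genes were called between IFE knockout and control libraries. Sex-linked genes were not called either, because the shared fit also counts the spread between the male and the female ORS control. At unadjusted p under 0.05 there were 1095 (479 higher, 616 lower), and limma-voom called 0. The fit without knockout E359 rests on knockout E358 alone. That library had reads in 12702 genes, the fewest in IFE, against 13556 in E359 and 13246 and 13887 in the controls. Steap4, a metalloreductase, was at 7.77 ± 0.88 CPM in controls and 0.081 ± 0.115 CPM in knockouts (log2 fold change -3.84, adjusted p = 0.0806). It passed with a filter at 50 reads (adjusted p = 0.0463), with all 12 libraries (0.00517) and on the deposited scale (0.0353). Without knockout E359 its log2 fold change was -4.06. The WNT effector Lef1 (log2 fold change 0.21, SE 0.362), the tumour suppressor Trp53 (0.22, SE 0.255) and the proliferation marker Mki67 (-0.34, SE 0.227) did not pass (adjusted p of 0.962, 0.905 and 0.813). The sign of Lef1 turned without knockout E358 (-0.15), and that of Trp53 without control E341 (-0.03).

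In ORS, sebaceous gland markers and genes of the epidermal lipid barrier and its proteases were lower in knockout than in control libraries. Of 16 tested sebaceous markers, 14 had a lower fitted level, with a median log2 fold change of -1.30 (-1.35 with genes at 0 reads at their bound). Elovl3, a fatty acid elongase of the sebaceous gland, was at 12.6 ± 10.4 CPM in controls and 0.057 ± 0.080 CPM in knockouts and was the only sebaceous marker lower when adjusted over the list alone (0 higher, 1 lower). Awat2, a wax ester synthase, was at 6.09 ± 2.13 and 0.604 ± 0.801 CPM, Awat1 at 2.25 ± 1.17 CPM with 0 reads in knockouts, and Mgst1, a microsomal glutathione transferase, at 121.3 ± 49.1 and 52.8 ± 15.3 CPM. The sebaceous list was called by camera (adjusted p = 4.82e-06, and adjusted p = 0.837 with an estimated correlation) but not without control E341 (adjusted p = 0.351, median -0.56). The median was -0.44 without knockout E358, where the call was kept (adjusted p = 0.0234).

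The ORS lipid barrier and protease list was lower by camera (20 tested, adjusted p = 0.00654, and adjusted p = 0.837 with an estimated correlation), with 0 members higher and 3 lower over the list alone. Klk7 and Klk5, serine proteases of skin desquamation, were at 15 ± 4.7 and 3.40 ± 1.04 CPM in controls, and at 0.056 ± 0.079 CPM and 0 reads in knockouts, with Klk5 at least 30-fold lower. Elovl1, an elongase of very long chain fatty acids, was at 99.8 ± 14.4 and 48.3 ± 8.8 CPM, and Klk11 at 2.43 ± 1.47 and 0.260 ± 0.368 CPM. The median log2 fold change was -0.82, and the call was lost without control E341 (adjusted p = 0.159, median -0.30) and without knockout E359 (0.39, median -0.49). Control E341 was also the male ORS library.

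Further ORS lists had single members that passed over the list alone, which is not corrected for the number of lists. Wnt3, a canonical WNT ligand, was at 1.36 ± 0.06 CPM in controls and 7.38 ± 0.56 CPM in knockouts (WNT list, 1 higher and 0 lower), with Wnt4 at 25.6 ± 0.5 and 44.1 ± 3.1 CPM. Egr1, an immediate-early transcription factor, was at 193.8 ± 61.3 and 26.1 ± 8.7 CPM (immediate-early list, 0 higher and 1 lower), and Fos and Fosb were at 80.7 ± 43.9 and 15.8 ± 3.0 CPM in controls and 19.0 ± 3.8 and 2.71 ± 1.27 CPM in knockouts. Krt6a, a stress keratin, was at 21.9 ± 14.9 and 0.861 ± 0.096 CPM, and Sprr1a, a cornified envelope precursor, at 19.4 ± 15.9 and 0.057 ± 0.080 CPM, each the 1 member lower in its list. The cornified envelope list as a whole had 18 of 24 members fitted above 0 in ORS, with a median log2 fold change of 1.14, and was not called (camera adjusted p = 0.279, and adjusted p = 0.921 with an estimated correlation). That direction rests on knockout E358, since the mean log2 level of the list was 4.10 there, 0.04 in knockout E359, and 2.30 and 0.50 in the controls. The immediate-early list as a group was not called (adjusted p = 0.0746), nor was the suprabasal list (adjusted p = 0.0746), with Krtdap at 223.1 ± 13.9 and 129.0 ± 50.4 CPM and Krt1 at 21.1 ± 23.2 and 2.99 ± 1.77 CPM. By limma, 0 of 14449 genes were called in ORS, 490 had an unadjusted p under 0.05 (195 higher, 295 lower), and limma-voom called 0. The 490 are fewer than would be expected if no gene differed, so this count is by itself no sign of change. Without control E344 the fit called 2 genes, Xist among them (adjusted p = 5.68e-05), since that control was the female of the pair. Lef1 (-0.02, SE 0.362), Trp53 (-0.25, SE 0.255), Mki67 (0.30, SE 0.227) and Xist (4.96, SE 3.33) did not pass, each with an adjusted p of 1. The sign of Lef1 turned without control E344 (0.13) and without knockout E359 (0.11), and that of Xist without control E341 (-0.06).

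In HFSC, genes that report signalling through the ERK kinase cascade were higher in the libraries labelled knockout. Of 15 tested ERK feedback and target genes, 12 had a higher fitted level, with a median log2 fold change of 0.76. Dusp6, a phosphatase that dampens ERK, was at 55 ± 0.9 CPM in controls and 146.6 ± 3.3 CPM in the libraries labelled knockout. Fosl1, an AP-1 factor, was at 0.658 ± 0.931 and 14.2 ± 5.7 CPM, and the ETS factors Etv5 and Etv4 were at 10.9 ± 4.1 and 2.82 ± 0.48 CPM in controls and 38.3 ± 7.0 and 16.7 ± 6.3 CPM in the libraries labelled knockout. Adjusted over the list alone, 5 members were higher and 0 lower. The list was called by camera (adjusted p = 0.00014, and adjusted p = 0.837 with an estimated correlation) and kept its call without each of the 4 libraries in turn (adjusted p between 0.000197 and 0.00255), with a median of 0.45 without knockout L97. Egfr transcript was 0.813 times the control in these libraries, and they were male against female controls.

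**Figure D4:**
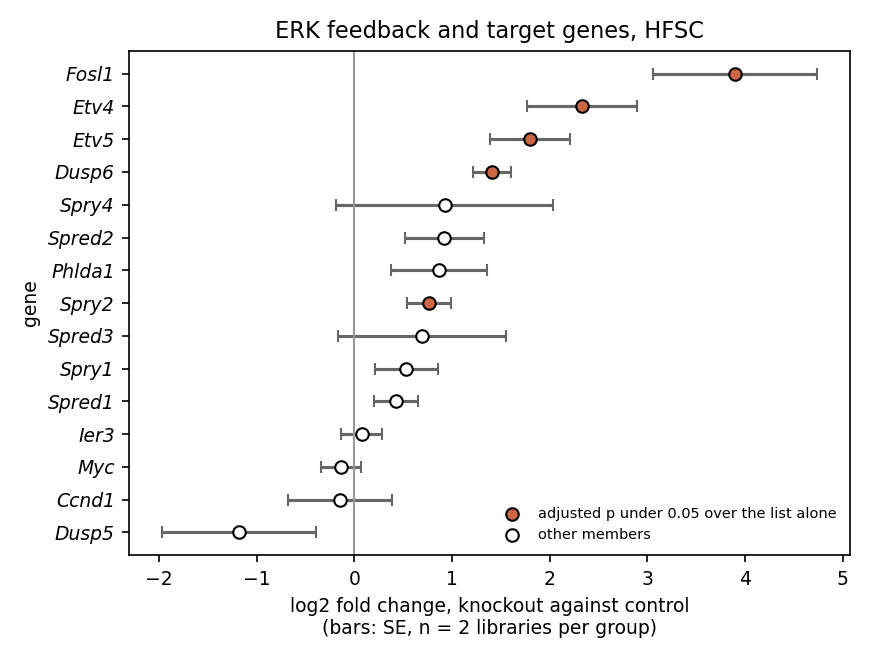
Log2 fold change of each ERK feedback and target gene in HFSC, libraries labelled knockout against control, with SE bars. Filled points are the 5 members with an adjusted p under 0.05 over the list alone, from Spry2 (0.76) to Fosl1 (3.89).

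By limma, 5 of 13778 genes were called in HFSC. Of these, 4 were sex-linked: Ddx3y, Eif2s3y and Uty rose from 0 reads to 138.2 ± 18.5, 120.0 ± 40.6 and 61.4 ± 22.9 CPM (at least 525-fold, 456-fold and 233-fold higher), and Xist fell from 582.2 ± 115.8 to 3.51 ± 3.29 CPM (adjusted p of 0.00679, 0.00795, 0.0236 and 0.0115). The sex-linked list was called by camera (adjusted p = 7.09e-06, and adjusted p = 0.837 with an estimated correlation), with 4 members higher and 1 lower over the list alone. There were 1047 genes at unadjusted p under 0.05 (573 higher, 474 lower), and limma-voom called 0. The fit called 19 genes without control L136, 27 without control L94, 2 without knockout L95 and 1 without knockout L97.

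Members of other HFSC lists passed in both directions over the list alone. In the stress list 2 were higher and 2 lower: Krt16, a keratin of activated epidermis, at 7.2 ± 7.3 CPM in controls and 147.5 ± 38.4 CPM in the libraries labelled knockout, Krt6a at 919.8 ± 161.8 and 1893 ± 208 CPM, Stfa3, a cystatin, at 22.6 ± 3.7 and 3.53 ± 0.09 CPM, and Defb6, a beta-defensin, at 56.2 ± 5.9 and 26.1 ± 0.9 CPM. In the outer root sheath and stem cell list 3 were higher and 2 lower. Ctgf, a matricellular protein, was at 158.3 ± 28.7 and 686.7 ± 308.1 CPM and Runx1, a transcription factor of stem cell activation, at 83.1 ± 36.8 and 178.2 ± 30.1 CPM, while Igfbp5, a binding protein of insulin-like growth factors, was at 141.8 ± 103.1 and 20.5 ± 15.2 CPM and Fgf18, a quiescence factor, at 89.7 ± 11.2 and 39.6 ± 13.6 CPM. In the basal list 1 was higher and 1 lower, Krt14 at 3935 ± 101 and 6179 ± 200 CPM and Krt15, a bulge keratin, at 34362 ± 2798 and 21141 ± 2930 CPM.

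In the HFSC WNT list 1 member was higher and 1 lower over the list alone, Lef1 at 2.89 ± 2.99 CPM in controls and 21.8 ± 4.6 CPM in the libraries labelled knockout (log2 fold change 3.05) and Sfrp1, a secreted WNT inhibitor, at 1266 ± 54 and 715.5 ± 32.2 CPM. The neutrophil chemoattractant Cxcl1 had 0 reads in controls and 6.28 ± 3.03 CPM (at least 23.8-fold higher, cytokine list, 1 higher and 0 lower). Krt77, a suprabasal keratin, was at 60.2 ± 22.3 and 12.5 ± 2.9 CPM (0 higher and 1 lower), Asprv1, an epidermal protease, at 7.22 ± 0.35 and 29.1 ± 5.5 CPM (lipid barrier and protease list, 1 higher and 0 lower), and Nrarp, a feedback gene of Notch signalling, at 18.2 ± 3.2 and 54.7 ± 0.9 CPM (1 higher and 0 lower). Sostdc1, a BMP and WNT antagonist, was at 1000 ± 246.9 and 552.6 ± 0.6 CPM (inner root sheath list, 0 higher and 1 lower). The EGFR ligand genes Tgfa and Hbegf were at 6.13 ± 3.87 and 8.02 ± 4.14 CPM in controls and 20.7 ± 7.3 and 17.9 ± 6.2 CPM in the libraries labelled knockout, and neither passed. None of these lists was called as a group. Trp53 (log2 fold change 0.05, SE 0.225, adjusted p = 0.981) and Mki67 (-0.21, SE 1.02, adjusted p = 0.98) did not pass. Mki67 was at 12.6 and 158 CPM in the libraries labelled knockout, and its sign turned without control L136 (0.39) and without knockout L95 (1.58). The sign of Trp53 turned without knockout L97 (-0.26).

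ORS and IFE libraries differed in follicle, differentiation and cell cycle genes. The titles of IFE and of ORS libraries carry different suffixes that no label explains, so a difference in handling or run between the compartments is not separable from the cell type. Of 23 tested outer root sheath and stem cell genes, 15 were higher in ORS and 1 lower (16 and 2 over the list alone). Lgr5, a receptor of follicle stem cells, rose from 1.12 ± 2.03 CPM in IFE to 396.9 ± 73.6 CPM in ORS (n = 4 each, both genotypes), Lhx2, a follicle transcription factor, from 4.41 ± 2.32 to 265.3 ± 40.4 CPM, and Sox9 from 273.8 ± 95.2 to 2144 ± 577 CPM. Of 18 suprabasal genes, 2 were higher and 10 lower (2 and 11 over the list alone), with Krt10 at 1002 ± 323 CPM in IFE and 42.6 ± 15.7 CPM in ORS, Krtdap at 4942 ± 322 and 176.1 ± 62.2 CPM, Dsg1a at 432.5 ± 107.8 and 19.1 ± 4.8 CPM, Dmkn at 4037 ± 501 and 1098 ± 244 CPM, and Krt1 at 1119 ± 464 and 12 ± 17 CPM. Mitotic and DNA replication genes were higher in ORS (11 of 29 and 9 of 27 called higher and 0 lower, 15 and 10 over the list alone), such as Mki67 (440.9 ± 114.7 and 940.4 ± 116.2 CPM), Top2a (502.2 ± 104.8 and 1089 ± 63 CPM) and Mcm2 (63.4 ± 35.8 and 208.4 ± 59.0 CPM).

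Over all genes, limma called 2277 of 14449 between ORS and IFE (1193 higher, 1084 lower). On the deposited scale, relative to a library total of which ORS libraries had the larger share in genes, 7113 were called (6644 higher, 469 lower), and the median log2 difference over genes was 1.11 in place of 0.11. Leaving out ORS control E341, ORS control E344 or ORS knockout E359 lowered the count to 1266, 1220 and 1488. With sex as a term it was 1140, where that term rests on the ORS control pair alone. With the title number as a fixed replicate block it was 177 (69 higher, 108 lower). That block leaves fewer residual degrees of freedom. It also takes out ORS control E344 and IFE control E360, whose numbers each occur in a single compartment. The lower count therefore does not show that the difference between the compartments is smaller. Camera called 14 of 33 lists, of which none passed with an estimated correlation (lowest adjusted p = 0.0715, for the outer root sheath list). The adjusted p of the called lists were 3.47e-09 for the outer root sheath list, 2.37e-07 for the suprabasal list, 8.69e-06 for each cell cycle list, 2.08e-05 for the stress list, 0.000237 for the lipid barrier, WNT and cytokine lists, 0.00228 for the basal list and 3.39e-11 for ribosomal protein genes.

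**Figure D5:**
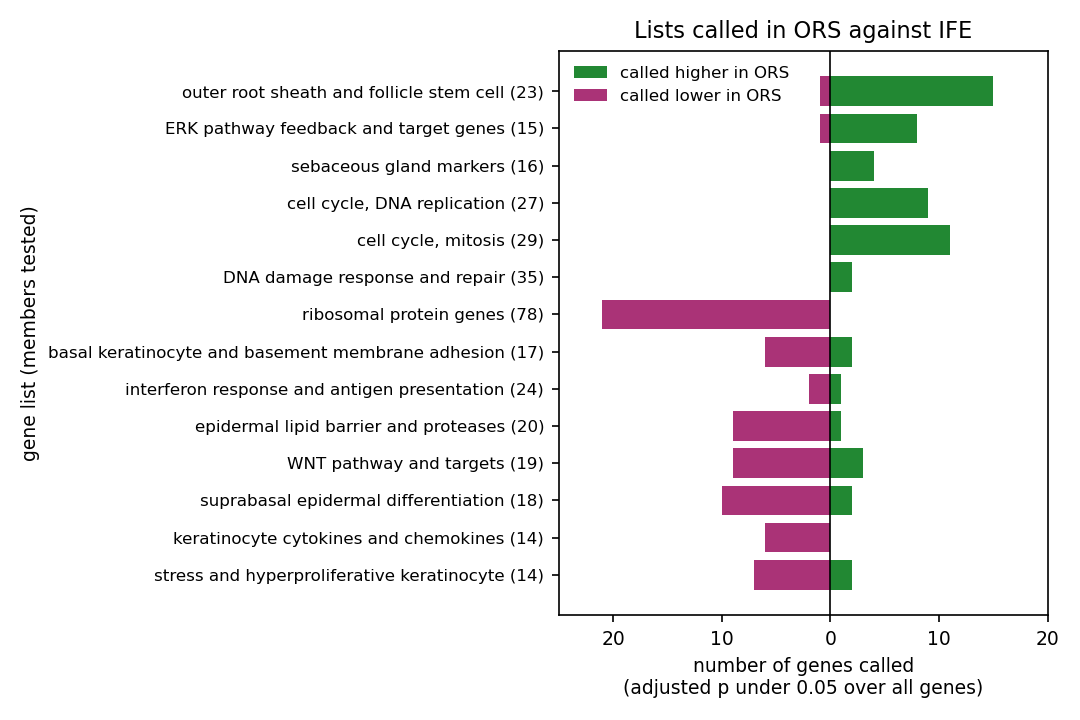
Number of genes called higher and lower in ORS than in IFE for each list called by camera, at adjusted p under 0.05 over all genes. The outer root sheath list holds 15 higher and 1 lower call, and the suprabasal list 2 higher and 10 lower.

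WNT ligands and their partners were lower in ORS (3 of 19 higher, 9 lower, with 4 and 10 over the list alone). Wnt3 fell from 287.7 ± 20.1 to 4.37 ± 3.49 CPM, Wnt4 from 464.3 ± 90.1 to 34.8 ± 10.8 CPM, the receptor Fzd10 from 158.6 ± 30.8 to 6.46 ± 1.96 CPM and Lef1 from 182.7 ± 43.5 to 18.6 ± 2.2 CPM. Stress list genes were also lower (2 of 14 higher, 7 lower, 2 and 9 over the list alone), among them the stefins Stfa3 (1559 ± 278 and 5.59 ± 6.23 CPM), BC100530 (3841 ± 706 and 7.42 ± 8.11 CPM) and Stfa1 (1437 ± 236 and 2.63 ± 3.69 CPM), whose reads may be shared. Of the lipid barrier and protease list 1 was higher and 9 lower (2 and 10 over the list alone), such as the kallikreins Klk10 (202.8 ± 33.9 and 13.6 ± 5.1 CPM) and Klk11 (130.4 ± 19.3 and 1.34 ± 1.53 CPM). Of 14 cytokine genes 0 were higher and 6 lower (0 and 7 over the list alone), with the T cell chemoattractant Ccl27a at 636.8 ± 192.6 and 24.9 ± 8.3 CPM, Il34 at 54.6 ± 10.8 and 5.08 ± 1.79 CPM, Cxcl14 at 395.6 ± 76.8 and 135.5 ± 61.8 CPM, and Cxcl10 at 23.0 ± 12 CPM in IFE with 0 reads in ORS (at least 199-fold lower). Basal genes had 2 higher and 6 lower of 17 (3 and 9 over the list alone). Krt14 fell from 9811 ± 1349 to 1648 ± 206 CPM, Krt5 from 9188 ± 1195 to 2986 ± 522 CPM and the hemidesmosomal collagen Col17a1 from 981.3 ± 105.8 to 523.3 ± 66.9 CPM (log2 -0.91, and 0.08 on the deposited scale). Of 78 ribosomal protein genes 0 were higher and 21 lower (0 and 34 over the list alone), with Rps3 at -0.65 and Rpl41 at -0.97 (log2), both of which turned on the deposited scale (0.34 and 0.02).

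Weaker list calls between ORS and IFE depended on single libraries. ERK targets (8 of 15 higher, 1 lower, 9 and 1 over the list alone, adjusted p = 0.0246) included Phlda1 (3.69 ± 2.47 and 81.4 ± 22.3 CPM), Ccnd1, the cyclin of early cell cycle entry (167.5 ± 26.5 and 418.6 ± 64.5 CPM), Spred1 (62.0 ± 19.5 and 176.3 ± 18.0 CPM) and, in the other direction, Myc (71.2 ± 24.6 and 4.89 ± 3.51 CPM). The call was lost without ORS knockout E358 (adjusted p = 0.0672) and IFE control E360 (0.0591). Sebaceous markers (4 of 16 higher and 0 lower, also over the list alone, adjusted p = 0.0317), among them Elovl5 (15.9 ± 13.5 and 127.3 ± 41.5 CPM) and Soat1 (1.38 ± 1.52 and 15 ± 10.5 CPM), lost the call without ORS control E341 (0.268), ORS control E344 (0.0745), IFE knockout E359 (0.0689) and ORS knockout E359 (0.128). Interferon genes (1 of 24 higher, 2 lower, also over the list alone, adjusted p = 0.0211), with Ifitm3 at 312.8 ± 85.0 and 75 ± 24.7 CPM and Usp18 at 14.4 ± 7.8 and 1.54 ± 2.08 CPM, lost it without ORS knockout E359 (0.0542). DNA damage genes (2 of 35 higher, 0 lower, 0 and 0 over the list alone, adjusted p = 0.044) included Fanca (10.2 ± 2.8 and 31.5 ± 15.9 CPM) and H2afx (58.4 ± 23.5 and 126.1 ± 31.7 CPM). Their call was lost without IFE control E341 (0.0682), IFE control E360 (0.0739), IFE knockout E358 (0.105), ORS control E344 (0.0959) and ORS knockout E359 (0.154).

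The inner root sheath list was not called between ORS and IFE (adjusted p = 0.645), with 4 of its 10 tested members higher and 1 lower, also over the list alone. Sostdc1, a BMP and WNT antagonist, rose from 407.4 ± 82.9 to 1480 ± 219 CPM, Cux1 from 41.3 ± 19.6 to 91.9 ± 17.2 CPM and Krt71 from 1.74 ± 3.48 to 10.4 ± 5.0 CPM, while Gata3 fell from 952.6 ± 77.2 to 323.2 ± 31.2 CPM. Krt28 had 0 reads in IFE and 2.33 ± 2.01 CPM in ORS (at least 8.59-fold higher). The hair shaft list was not called (adjusted p = 0.613), with 2 of 15 members higher and 1 lower (2 and 4 over the list alone), 9 fitted below 0 and a median log2 difference of -0.58, and the keratin-associated list was not called either (adjusted p = 0.401, 1 of 4 higher and 1 lower, 2 and 1 over the list alone). Of the members that were higher, the regulators Prdm1 and Hoxc13 had 0 reads in IFE and 80.9 ± 23.3 and 52.1 ± 12.9 CPM in ORS (at least 299-fold and 192-fold higher), and the hair keratin-associated gene Krtap17-1 had 0 reads in IFE and 48.7 ± 5.4 CPM in ORS (at least 180-fold higher).

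The knockout effect on cornified envelope genes differed between ORS and IFE. Of 24 tested members, 21 had a higher effect in ORS, with a median log2 difference of 3.66 (camera adjusted p = 2.11e-05, and adjusted p = 0.609 with an estimated correlation). The call was lost without IFE control E341 (adjusted p = 0.219, median 2.29) and without ORS knockout E358 (0.109, median 1.49), and the median was 5.77 without ORS knockout E359. The lowest p with a higher effect in ORS belonged to Krt78, a differentiation keratin (IFE 6.92 ± 5.02 CPM in controls with 0 reads in knockouts, ORS 0.018 ± 0.025 and 9.32 ± 3.36 CPM), Steap4 (ORS 348.6 ± 16.8 and 363.3 ± 193.1 CPM), Kbtbd7 (IFE 15.5 ± 8.2 and 0.284 ± 0.401 CPM, ORS 14.7 ± 6.9 and 42.5 ± 5.0 CPM), the ubiquitin ligase Wwp1 (log2 difference 3.23) and Zfp773 (6.89). With a lower effect in ORS they were Tmem106a (-6.49), Pi15 (IFE 16.9 ± 3.1 and 51.4 ± 22.0 CPM, ORS 63.7 ± 6.4 and 19.7 ± 4.1 CPM), Enc1, an actin-binding protein (-4.71), and Rps6ka6, an ERK-regulated kinase (-3.01). None passed (adjusted p = 0.999). By limma 0 of 14449 genes were called for this difference, 687 had an unadjusted p under 0.05 (318 higher, 369 lower), and limma-voom called 0. The 687 are also fewer than would be expected if no gene differed. Egfr differed by 3.63 (SE 1.35, adjusted p = 0.999). Without ORS control E341 all ORS libraries left were female, and the sex-linked Xist and Tsix differed by -9.55 and -8.31. Because IFE controls were male and IFE knockouts female, these 2 values follow the sexes and show no effect of Egfr. Without IFE knockout E359, Sgk1 differed by 5.46. No gene was called in both IFE and ORS. At unadjusted p under 0.05, 11 genes were higher in both (6.5 if independent) and 14 lower (12.6 if independent), including Egfr and Krt6a.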

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

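All tests weighed in this part were chosen only after the result was seen: exchanged labels, a counted deleted transcript, deletion in part of the cells, a single library, sex, and low levels. The knockout effect on cornified envelope genes differed between ORS and IFE (camera adjusted p = 2.11e-05 for the difference itself, and adjusted p = 0.609 with an estimated correlation), a call lost without IFE control E341 (0.219) and without ORS knockout E358 (0.109).

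In IFE, cornified envelope genes were lower in knockouts. Without IFE control E341 the highest p was 0.138, so the pattern may rest on that library, whose title number is shared with ORS control E341. Sex stays open. In the ORS control pair the list was higher in the male library, which is E341 (median log2 difference 2.25). Both IFE controls were male, yet the mean log2 level of the list was 4.76 in E341 and 1.75 in E360. The female IFE knockouts were at 0.93 and 0.73. Sex alone thus does not account for the gap between the IFE controls. IFE holds no control of the other sex, so sex and genotype cannot be told apart. A biological effect of Egfr loss was not separable from either.

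Egfr reads remained in the HFSC libraries labelled knockout. An exchange of the labels of both groups together with a large loss of Egfr is argued against. The labelled controls held 76.6 CPM more than the labelled knockouts, a difference larger than the SD in either group. An exchange with little or no loss cannot be decided, because the 95% interval of the fold includes no difference. A deleted transcript that is still counted is argued against by IFE, where 0.119% of the control level was left, if the same floxed allele was used. Deletion in a part of the sampled cells may apply, but the 95% interval of the fold reached 1.04 and so also allows no reduction. The sampling of cells that keep the receptor was not tested.

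ERK feedback genes were higher in the HFSC libraries labelled knockout by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.837). At the preset correlation a single library is argued against, since the highest p over the fits without each library in turn was 0.000106, although the median fell from 0.76 to 0.45 without L97. Sex remains open: the list's median was 0.128 higher in the male than in the female ORS control library, with only 1 library per sex, and 0 in IFE (male controls minus female knockouts), where sex and genotype coincide. Low levels cannot be told apart from a true change by the test run, because it used the pattern's own top genes, although 3 of the 5 members that passed over the list alone (Dusp6, Spry2 and Etv5) averaged at least 20 CPM. A link to Egfr is a hypothesis at most, since Egfr transcript was largely kept.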

How the results depend on the processing

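The tests on pseudocount, deposited scale, sex and removal of sex-linked genes were chosen only after the results were seen, and the fixed block was fitted in limma because the planned count tool was not used. The DESeq2 Wald test was not run. Where an arm was left with 1 library, that library is assumed to vary like the other groups. In IFE the count of 0 calls became 3 with at least 50 reads, 5 with the compartment's own libraries, 24 with all 12 libraries and 1 on the deposited scale, and ranged from 0 to 53 on leaving out a library. In ORS that range was 0 to 2, and for the difference of effects 0 to 2. In HFSC the 5 calls became 0 without a filter, 0 with limma-voom, 1 with all 12 libraries, 2 on the deposited scale and 0 without Xist and Y-linked genes, and ranged from 1 to 27 without a library. Of ORS against IFE, 7113 were called on the deposited scale, 1140 with sex as a term and 1220 to 2688 without a library. The 7 knockout lists called became 0 with an estimated correlation, 1 with fry, and 4 to 13 without a library. Apart from the settings by construction (fewer genes, samples or residual degrees of freedom), the cause was not tested.

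Title numbers do not pair libraries in the labels. With the title number as a fixed replicate block in the limma fit, 177 genes (69 higher, 108 lower) were called between ORS and IFE (2277 without it). As a random effect with limma-voom, 2515 were called (2219 without it). The fixed block leaves fewer residual degrees of freedom and takes ORS control E344 and IFE control E360 out of the comparison. The E358 minus E359 difference correlated at 0.056 between IFE and ORS over genes, which are not independent. The estimated correlation of libraries with the same title number was 0.123.

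Signs turned with sex as a term for Lef1 (-0.0938), Trp53 (-0.0216), Ddx3y (0.55), Uty (0.86), Xist (-0.55) and Krt1 (2.74) in IFE and for Xist (-0.0599) in ORS. Sex varied within a group only in the ORS controls (E341 male, E344 female), so the term rests on that pair. The IFE values with this term are the IFE effects shifted by the difference of that pair. They do not separate genotype from sex in IFE. On the deposited scale they turned for Krt10 in IFE (-0.0227), Trp53 in HFSC (-0.00898) and for Col17a1 (0.0827), Rps3 (0.345) and Rpl41 (0.0212) in ORS against IFE. Krt10 in IFE, near 0, also turned with another scaling (-0.000938), no filter (-0.00725), limma-voom (-0.00349) and all 12 libraries (-0.0200). Leaving out a library moved Krt1 between -0.78 and 0.50 and Krt10 between -0.56 and 0.55 in IFE, Lef1 between -0.15 and 0.54 in IFE and between -0.17 and 0.13 in ORS, Trp53 between -0.0333 and 0.45 in IFE and between -0.26 and 0.33 in HFSC, Xist between -0.0595 and 9.98 in ORS, and Mki67 between -2.02 and 1.58 in HFSC. Of all values of named genes, 482 of 514 in IFE, 351 of 378 in HFSC, 915 of 987 in ORS against IFE and 190 of 190 for the difference kept direction and side of the threshold. In ORS, of 346 such values 4 were reversed, 1 was stronger and the others kept both.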

Other observations

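The correlations of fold changes were chosen only after the results were seen, while the splits of the ORS and IFE libraries were planned before. Across genes, which are not independent replicates, knockout log2 fold changes were nearly unrelated between compartments (Pearson r of 0.036 for IFE and ORS, -0.023 for IFE and HFSC, and -0.022 for ORS and HFSC). With 2 libraries per group and 0 genes called in IFE and in ORS, scatter between libraries can by itself bring r near 0. These values therefore do not show that the effects differ between compartments.

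In 35 splits of the 8 IFE and ORS libraries into 4 and 4, only the real split gave as many calls (1 of 35). It gave 2465 calls in a model of 2 groups, and the highest of the other splits gave 0. Each other split holds libraries of both compartments in both arms, so a compartment difference adds to its residual spread and lowers its calls. That 0 is therefore no measure of the calls that arise without a difference. The smallest share these splits can give is 1 of 35, and they treat the libraries as exchangeable, although 3 title numbers occur in both compartments. With the title number as a fixed replicate block, which leaves fewer residual degrees of freedom, 177 genes were called.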
